A study of Mus musculus with 16 samples.

How the data were processed

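RNA was extracted from endothelial cells isolated from the cerebral cortex of mice, without culture, and polyadenylated RNA was sequenced as strand-specific libraries, per the labels' protocols. Cells were selected with magnetic beads against CD31, a surface protein of endothelial cells, after myelin and CD45-positive blood and immune cells had been depleted. Cell suspensions of 2 mice were pooled for each library, so the 16 libraries stand for 32 mice. The 4 groups were 16p11.2 df/+ mice and wild-type (WT) littermates at postnatal day 14 (P14) and postnatal day 50 (P50), with 4 libraries in each, and the titles number them 1 to 4 within a group. P-values therefore measure the spread between pools of mice, with 1 estimate per gene shared by the 4 groups. Labels were used as given; the sex of the mice is not given in the sources used here.

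The deposited gene table holds raw read counts per Ensembl gene for the 16 libraries. Reads were aligned with STAR 2.5.3a to GRCm38.p5 and DESeq2 was used, per the submitters' processing notes; the DESeq2 version, the counting tool, its strand setting and the gene annotation are not given in the sources used here. A second table deposited by the authors holds a normalized signal, which equalled the count divided by 1 size factor per library to within 0.000138. It was used only for this check. The deposited mapping summary gives, per the file headers, read counts, mapped reads as a fraction of the input reads and other values such as the read length, which was 133 to 134 bases per library. These values were used to describe the libraries and entered no test.

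The count table holds 52636 gene IDs, of which 52403 have a symbol and 233 have none; 147 symbols are shared by more than 1 ID. IDs without a symbol held 0.0296% to 0.0508% of the counts. Total counts were 8658792 to 18737781 per library, from 10688859 to 23065297 input reads. Between 94.7% and 98.1% of reads mapped, 85.6% to 92.3% mapped to 1 place, and 87.0% to 91.2% of the uniquely mapped reads were counted in genes. A chi-square test of the counts separated every pair of replicates, with chi-square per degree of freedom of 7.09 to 318, so no library was counted as a repeat of another. Because the strand setting of the counting is not known here, values of overlapping genes on opposite strands are uncertain. Intervals and floors given for genes with few reads cover counting error only, since the reads carry no molecular identifiers; a count of 0 was set against a floor of 3 reads over the group.

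Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 (legacy dispersion method) in R 4.3.3, with TMM normalization factors (0.917 to 1.05) and 1 mean per group, on all 16 libraries. Genes were kept by filterByExpr with a minimum count of 10, equal to 0.647 CPM (counts per megaread) in 4 libraries, which left 15368 genes holding at least 99.6% of the counts of every library. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene was called at an adjusted p under 0.05. The fit had 12 residual degrees of freedom and a biological coefficient of variation of 29.1%. Replicates differed more at P50: chi-square per degree of freedom between them was 7.09 to 34.2 at P14 and 35.7 to 318 at P50. As the spread is shared, p-values at each age rest partly on the other age. With only the 8 libraries of a comparison, genes at an unadjusted p under 0.05 went from 362 to 1216 at P14 and from 655 to 215 at P50. The comparisons were genotype (df/+ against WT) at P14, at P50 and averaged over both ages, the difference of the genotype effects between ages, and age (P50 against P14) within each genotype. Log2 fold changes are given with their standard error (SE), and levels as CPM, mean ± SD of 4 libraries.

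Gene lists, 36 in number, were fixed together with the tests and the alternatives before the data were examined: the genes of the deleted interval and of its flanks, 10 endothelial programmes, markers of 12 other cell types, 9 cell processes and 3 quality lists. Of 907 entries, 904 matched the table. The 35 lists with 5 or more tested members were compared with all other genes by camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation between genes of 0.01), adjusted over the 35 lists. The list of sex-linked genes had too few members and was not tested. Because genes of a list vary together, each camera result was repeated with a correlation estimated from the libraries, and with fry, which asks whether the genes of a list move on balance in 1 direction. Of the lists called with the preset correlation, 3 of 15 held with an estimated correlation at P14 (deleted interval, microglia and perivascular macrophage), 1 of 9 at P50 and 1 of 13 in the averaged comparison (deleted interval in both), 0 of 12 in the comparison of the ages, 0 of 10 for age in WT and 0 of 14 for age in df/+. Fry called 1 list at P14, at P50 and in the averaged comparison, 0 between the ages, 15 for age in WT and 16 for age in df/+. Called members were counted over all genes and adjusted over the list alone.

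Named genes followed a fixed rule. It took the tested genes of the deleted interval, and Nos3, Pecam1, Kdr and Gapdh, for which the labels give qPCR primers. Outside the interval it took called genes that reached 4 CPM in the higher group and whose libraries did not overlap between groups. These were ranked by size, leaving out gene models. It also took the members with the smallest p-value of each list reported, whether or not the list was called. Tyr, whose levels lie under the minimum of 4 CPM, and Zswim1 in the averaged comparison were named outside this rule, after their values were seen.

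The labels number the libraries 1 to 16 without saying what the number means: P14 WT and P50 df/+ have 1 to 8, and P14 df/+ and P50 WT have 9 to 16. This split was treated as a possible batch, although no source used here says that the 2 ranges were processed apart. Each range holds 1 genotype per age and 1 age per genotype, so neither the genotypes at 1 age nor the ages in 1 genotype could be compared within a range. The averaged comparison balances the ranges, and the interaction equals their difference. The replicate numbers were checked as pairs by the correlation of the libraries' deviations from their group means. Between P14 WT and P50 WT the same-number correlations were 0.111 to 0.239, all 4 above 0.1, which passed the rule set for this check. Of these, 3 of 4 libraries correlated best with their own number. The labels state no shared litter or day, and in P50 WT the animal numbers in the library labels differ from the replicate numbers of the titles. A pairing is therefore not established.

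The pipeline was tested on simulated data drawn from the real means and library sizes. Apart from 1 shifted list, changes were planted only in genes outside the lists with a mean of at least 2 CPM. Recovery of changes in genes under that level was not measured. In the P14 simulation (15083 genes) 10.4% of genes changed 1.5-fold, 41.8% of those changed 2-fold and 84.8% of those changed 4-fold were called, and 2 of 94 calls were false; in the P50 simulation (15041 genes) the shares were 14.9%, 37.3% and 87.9%, and 4 of 99 calls were false. No gene was called where nothing had been changed. A list shifted by 1.3-fold was called in both. The simulated genes varied independently of each other, without the correlation between genes and the length trends of the real libraries. The simulation therefore does not show how many false calls of genes or lists such structure gives.

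The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a filter of 1 CPM in 4 libraries, only the 8 libraries of a comparison, a replicate block, a term for the number range (for the averaged comparison the same fit as the 4 group means, so no separate check), 1 surrogate variable (sva 3.50.0), removal of mitochondrial, haemoglobin and Y-linked genes, other thresholds, and each library left out in turn. Added after seeing the data were the newer quasi-likelihood method of edgeR, an offset for each library's trend with transcript length and GC content (available for 15348 genes), and a fit without 2 doubted libraries. Measurements other than RNA sequencing that the labels mention were not analysed here.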

Results

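RNA was sequenced from endothelial cells taken directly from the cerebral cortex of 16p11.2 df/+ mice and of their wild-type (WT) littermates. The df/+ mice lack 1 copy of an interval of chromosome 7 that corresponds to human 16p11.2, a region whose deletion is associated with autism. The study asked for a vascular contribution to this syndrome. The libraries compared the genotypes at postnatal day 14 (P14), while the cortical vasculature is still maturing, and at postnatal day 50 (P50). Each of the 4 groups held 4 libraries, and each library held the cells of 2 mice. Total counts per library were 12484207 to 17178787 in P14 WT, 8658792 to 18063589 in P14 df/+, 14303921 to 17639603 in P50 WT and 15611059 to 18737781 in P50 df/+. Replicate 2 of P14 df/+ had the lowest total. Of the genes of the table, 15368 were abundant enough to be tested. The leading principal component held 52.4% of the variance and separated the ages, with scores of -64.6 to -45.8 at P14 and 22.3 to 132 at P50. The next component held 18.4%, and replicate 2 of P50 df/+ stood at 92.0 on it while the other 15 libraries lay between -54.0 and 32.8.

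The deleted interval was examined first, since its genes show whether the libraries carry the genotype in their label. Genes from Slx1b to Sept1 (GRCm38 chromosome 7, 126689468 to 127233130, 544 kb, 37 protein-coding genes in the table) had about 0.5 times their WT level in df/+ cells at both ages. All 26 tested genes of the list were lower in df/+, with a median log2 fold change of -1.11 at P14 (0.462 times WT) and -0.94 at P50 (0.522 times WT). Taok2, which encodes a kinase, fell from 324 ± 28.4 to 147 ± 7.20 CPM at P14 (SD, n = 4) and from 246 ± 16.9 to 116 ± 21.0 CPM at P50. Its log2 fold changes were -1.14 (SE 0.126) and -1.08 (SE 0.125), with adjusted p = 0.00188 and 0.00204 by the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment. Maz, a zinc finger transcription factor, fell by 1.08 and 0.95 on the log2 scale (adjusted p = 0.00188 and 0.00440), and Tbc1d10b fell by 1.05 and 1.01 (adjusted p = 0.00188 and 0.00280). Mapk3, which encodes the kinase ERK1, fell from 319 ± 32.7 to 148 ± 9.05 CPM at P14 (log2 fold change -1.11, adjusted p = 0.0221), a call lost without any 1 of the P14 libraries except replicate 1 of WT (0.0780 to 0.156). Its value at P50 was -0.94 (413 ± 42.4 against 215 ± 63.8 CPM, adjusted p = 0.0720, and 0.00305 without replicate 2 of P50 df/+). Kctd13, Aldoa and Mvp, other genes of the interval, had log2 values of -0.70, -1.06 and -1.10 at P14 and of -0.93, -0.73 and -0.98 at P50. They did not pass the test at either age. Mvp passed at P14 without replicate 1 of P14 WT (adjusted p = 0.0493) and at P50 without replicate 2 of P50 df/+ (0.00197).

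Of the 26 list members, 9 were called at P14 over all genes and 21 adjusted over the list alone. At P50 these counts were 5 and 21, and with the ages averaged they were 14 and 25. By coordinates 29 tested genes lie in the interval. All 29 were lower in df/+ at both ages, and 10 and 6 were called. Besides the genes above, Cd2bp2 (-1.19), Fam57b (-1.25), Hirip3 (-1.17), Ino80e (-1.10), Slx1b (-1.11) and AI467606 (-1.13) were called at P14, and Fam57b (-1.31), Hirip3 (-1.16) and AI467606 (-1.21) at P50. Taok2, Maz and Tbc1d10b kept both calls in all 8 omissions of 1 library per age. At P14 AI467606 kept its call in 5 of 8, Cd2bp2 in 2 (highest adjusted p = 0.117), and Fam57b, Hirip3, Ino80e and Slx1b in 1 each (highest 0.193, 0.248, 0.195 and 0.185). At P50 Fam57b kept it in 4 of 8, Hirip3 in 2 (highest 0.130 and 0.184) and AI467606 in all. Slx1b overlaps Bola2, Fam57b overlaps Aldoa, Ino80e overlaps Hirip3 and Kctd13 overlaps Asphd1 by coordinates, so their single values are uncertain. In camera the list was lower with adjusted p = 6.25e-75 at P14 and 6.16e-48 at P50 (adjusted p = 6.25e-04 and 0.00511 with an estimated correlation). None of the 33 tested genes in the flanks of the interval was called at P14 or P50, over all genes or adjusted over the list alone, and their median log2 fold changes were -0.08 and 0.00. Of these, 25 and 16 were lower in df/+ (camera adjusted p = 0.0881 and 0.489). At P50 the list was called without replicate 2 of P50 df/+ (median -0.12, adjusted p = 0.00351).

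**Figure D1:**
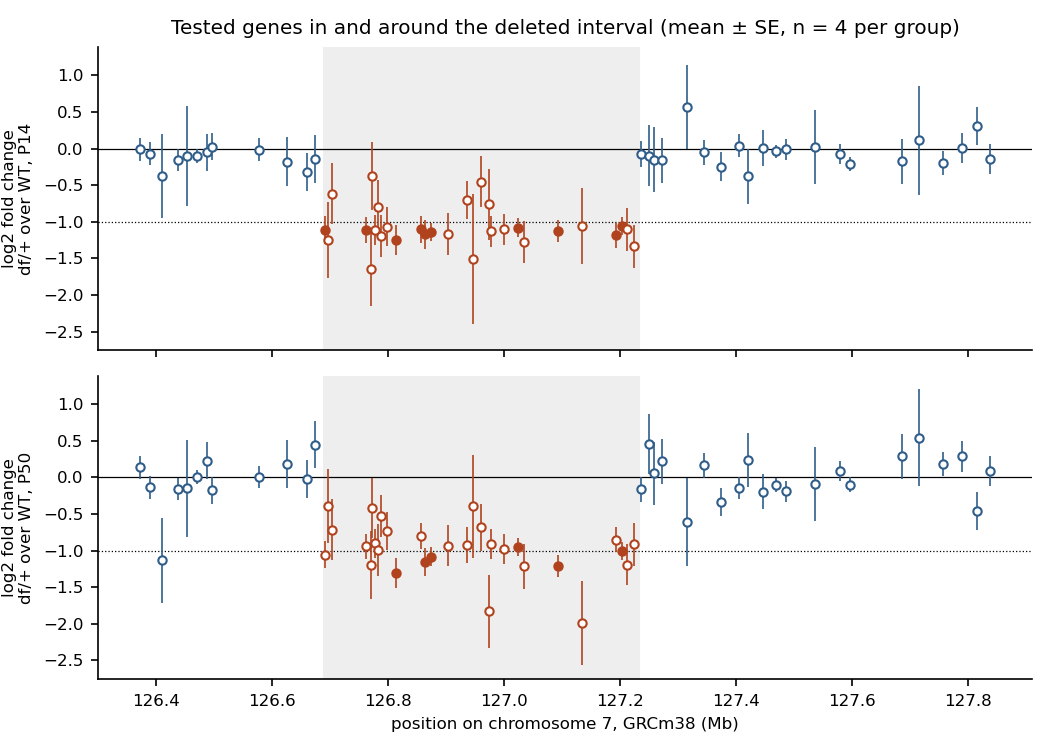
Log2 fold change (df/+ over WT, vertical axis, bars ± SE of the fit, n = 4 libraries per group) of tested genes against their position on chromosome 7 (horizontal axis), at P14 in 1 panel and at P50 in the other. Red points in the grey band are genes of the deleted interval, filled where called, blue points are flanking genes, and the dotted line marks -1; all 29 interval genes lie under 0 at both ages.

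Per library, the median log2 ratio of the interval genes to same-age WT libraries was -1.03, -1.16, -1.15 and -1.06 in the P14 df/+ replicates 1 to 4, and -0.17 to 0.10 in P14 WT. At P50 the spread was larger: -0.87, -0.49, -1.26 and -1.31 in df/+ and -0.40, 0.17, -0.14 and 0.34 in WT. Replicate 2 of P50 df/+ thus retained 0.710 times the WT level, the highest value among the 8 df/+ libraries. The P50 libraries also differed in how counts depended on transcript length. Relative to the median of the libraries of the same age, the slope per doubling of length ranged from -0.481 (replicate 2 of P50 df/+) and -0.234 (replicate 4 of P50 WT) to 0.236 (replicate 3 of P50 df/+), while P14 slopes lay between -0.0894 and 0.0508. With each library's length and GC trend removed, an alternative chosen after seeing the data, the interval ratios of the P50 df/+ libraries were -0.97, -0.79, -1.05 and -1.12 and those of P50 WT lay between -0.10 and 0.03. The SD fell from 0.383 to 0.143 in df/+ and from 0.327 to 0.0593 in WT.

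**Figure D2:**
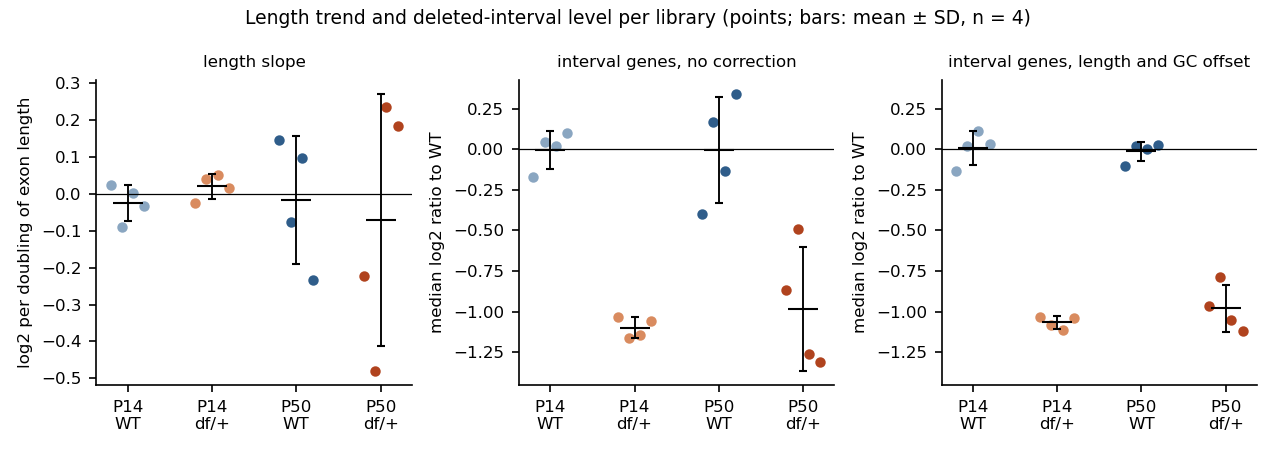
Slope of log2 CPM on transcript length for each library (log2 per doubling of length, relative to the median of the same age), beside the median log2 ratio of the interval genes to same-age WT before and after each library's length and GC trend was removed. Points are single libraries of the 4 groups; the P50 libraries spread from -0.481 to 0.236 in slope, and their interval ratios draw together after the correction.

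At P14 the genotypes were compared to ask whether the deletion alters cortical endothelial cells beyond the interval itself. Of 15368 genes, 10 were called by edgeR, all of them lower in df/+ and all inside the interval. Outside the interval 0 genes were called. Of all tested genes 362, or 2.36%, had an unadjusted p under 0.05, fewer than the share of 0.05 expected if no gene differed. DESeq2 called 23 genes, of which 8 lay outside the interval, nonagouti and Tyr among them, and limma-voom 7 with 0 outside. Transcripts of the endothelial nitric oxide synthase Nos3 were at 468 ± 51.4 CPM in WT and 417 ± 10.3 CPM in df/+ (SD, n = 4; log2 fold change -0.17, SE 0.135). Those of Pecam1, which encodes CD31, were at 1378 ± 52.5 and 1339 ± 53.1 CPM (-0.04, SE 0.119). Those of the VEGF receptor Kdr were at 2582 ± 140 and 2687 ± 217 CPM (0.06, SE 0.234). The metabolic gene Gapdh had a log2 fold change of -0.02 (SE 0.240). None of these 4 genes was called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.00 for each). The count of 10 depended on single libraries: it was 73 without replicate 1 of P14 WT (58 outside the interval), 4 without replicate 2 or 3 of WT or replicate 1 of df/+, 5 without replicate 4 of WT, and 3 without replicate 2, 3 or 4 of df/+. With upper-quartile scaling it was 5, with only the 8 P14 libraries 22 (4 outside), with 1 surrogate variable 21 (3 outside) and with the replicate number as a block 3. Without both doubted libraries, replicate 1 of P14 WT and replicate 2 of P50 df/+, it was 137 (120 outside), a fit chosen after seeing the data. The labels also number the libraries 1 to 16. At P14 the WT libraries had numbers up to 8 and the df/+ libraries numbers from 9, so this number range and the genotype cannot be told apart.

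None of the 10 endothelial lists was called between genotypes at P14. Median log2 fold changes were -0.05 for endothelial identity (33 genes, camera adjusted p = 0.274), -0.03 for blood-brain barrier transporters and junctions (33 genes, 0.421), -0.08 for VEGF signalling and tip cells (31 genes, 0.315). They were -0.03 for Notch and arterial genes (0.895), -0.01 for venous genes (0.895), -0.05 for vasoreactivity and nitric oxide (0.847), -0.01 for Wnt targets (0.847), 0.03 for TGF-beta and BMP signalling (0.0676), -0.02 for basement membrane (0.813) and -0.01 for adhesion and leukocyte traffic (0.312). For the venous, vasoreactivity and adhesion lists the mean and the direction of the test were above 0 while the median was under it, and for basement membrane only the mean was above 0. Members with the smallest p-values included Ecscr (-0.42), Tie1 (-0.17), the transporter Slco1a4 (0.29), Slc3a2 (-0.18), Mcam (-0.19), Vegfa (0.31), Ptgs1 (0.46), Trpv4 (0.67), and the Wnt targets Notum (-0.19) and Lef1 (-0.10). None of them was called. Adjusted over the list alone, 1 gene of the adhesion list and 0 of the other 9 lists passed. Without replicate 2 of P14 df/+ the TGF-beta and BMP list was called (0.0126), and with 1 surrogate variable the endothelial identity list (median -0.09, 0.0288).

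Markers of other cells were higher in P14 df/+ libraries. Of 20 tested microglia markers, 19 were higher, with a median log2 fold change of 1.57 (camera adjusted p = 5.62e-32; adjusted p = 0.0283 with an estimated correlation). Of 10 markers of perivascular macrophages 9 were higher, with a median of 1.40 (1.98e-16; adjusted p = 0.0283 with an estimated correlation). The microglial receptor P2ry12 was at 2.22 ± 2.70 CPM in WT and 7.89 ± 2.28 CPM in df/+ (SD, n = 4; log2 fold change 1.85, SE 0.620). Csf1r, the receptor of macrophage colony-stimulating factor, was at 17.5 ± 19.6 and 53.5 ± 9.70 CPM (1.62, SE 0.548), and the scavenger receptor Cd163 was at 3.54 ± 3.70 and 10.8 ± 2.24 CPM (1.61, SE 0.488). No member of either list was called over all genes; adjusted over the list alone, 0 of 20 and 1 of 10 passed. Without replicate 1 of P14 WT, P2ry12, Csf1r and Cd163 were called (log2 fold change 3.17, 2.78 and 2.65, edgeR adjusted p = 0.0128, 0.00601 and 0.00299), 15 members of the 2 lists rose, and the list medians were 2.79 and 2.49. Per library, with the P14 WT mean as 0, the microglia list stood at 1.36 to 1.87 in the 4 df/+ libraries, at -0.25, -0.52 and -0.89 in replicates 2, 3 and 4 of WT, and at 1.67 in replicate 1 of WT. The difference between the group means of this list was 1.68 (SE 0.583; exact 2-sided permutation test, p = 0.0571, where 0.0286 is the smallest p that 4 against 4 libraries allow; Benjamini-Hochberg adjusted p = 0.333 over the lists).

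Other brain cell lists were higher as well. All 18 astrocyte markers were higher (median 0.47, camera adjusted p = 1.69e-09; adjusted p = 0.165 with an estimated correlation), with Slc1a3 at 175 ± 45.7 and 274 ± 52.7 CPM. The neuron list (median 0.79, 18 of 20 higher), the oligodendrocyte list (0.42, 12 of 16) and the precursor list (0.57, 12 of 13) each had a camera adjusted p = 2.78e-06 and adjusted p = 0.404, 0.432 and 0.165 with an estimated correlation. The fibroblast list had 0.00265 (median 0.23, 13 of 17 higher; adjusted p = 0.339 with an estimated correlation). Example log2 values were 2.98 for Gad2, 2.07 for Snap25, 0.47 for Enpp2, 0.57 for Pdgfra, 0.71 for Tnr and 0.98 for Lum, none called. With replicate 1 of P14 df/+ left out, Gad2 was at 0.98 and Snap25 at -0.36, and with replicate 3 left out Enpp2 was at -0.12. Pericyte (median -0.11, adjusted p = 0.0811), smooth muscle (0.13, 0.0676), erythrocyte and platelet (0.23, 0.223) and lymphocyte and neutrophil markers (0.08, 0.656) were not called. Neither were ependymal markers (0.813), for which the test pointed down while the median and mean of the fitted log2 fold changes were 0.49. The difference in mean log2 CPM of this list was -0.18 (SE 0.798). The oligodendrocyte and precursor medians were 1.99 and 1.01 without replicate 1 of P14 WT, and the oligodendrocyte median was 0.05 without replicate 3. Without replicate 1 of P14 df/+ the neuron list had a median of 0.06 (adjusted p = 0.187) and the fibroblast list an adjusted p = 0.0857. The pericyte list was called as lower without replicate 2 or 3 of P14 WT or replicate 1 of P14 df/+ (0.0129, 0.0417, 0.00820). The smooth muscle list was called as higher without replicate 3 or 4 of P14 WT or replicate 1 of P14 df/+ (0.0214, 0.00513, 0.0159). The ependymal list was called without replicate 2 of P14 df/+ (median 0.84, 0.0336) or replicate 3 (-0.09, 0.0103).

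**Figure D3:**
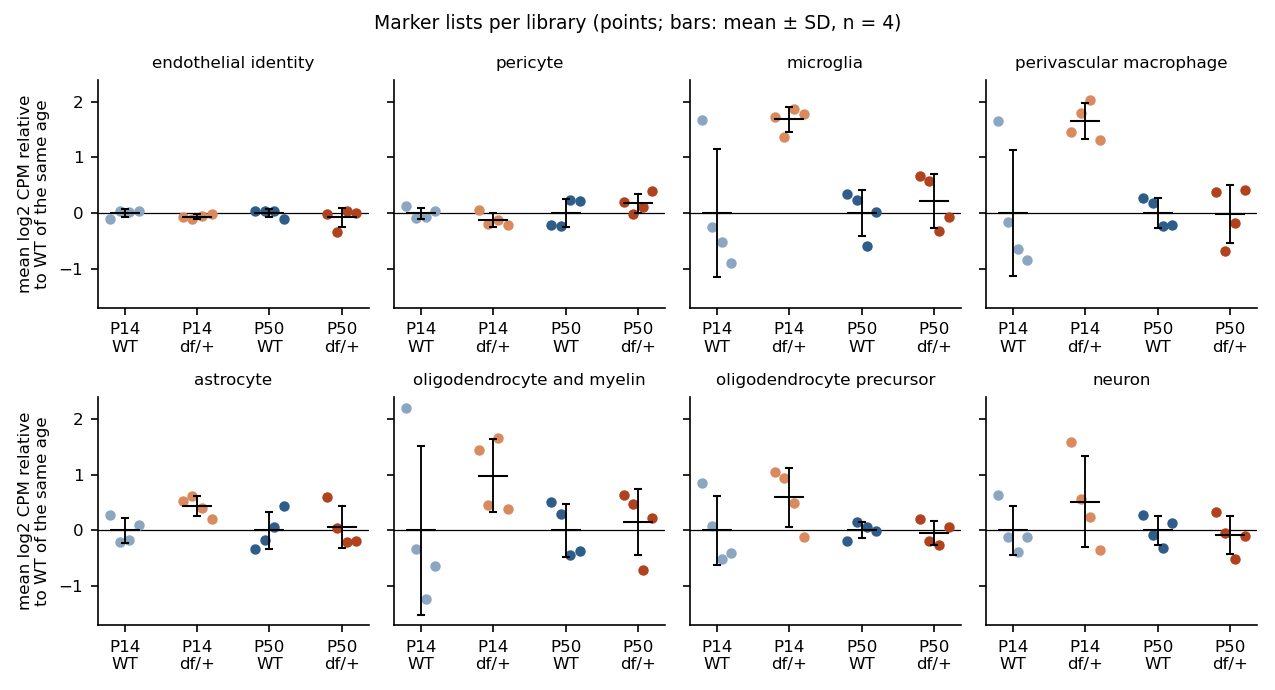
Mean log2 CPM of 8 marker lists per library, relative to the mean of WT libraries of the same age (vertical axis), by genotype and age (horizontal axis); points are libraries and bars mean ± SD, n = 4. For microglia at P14 the df/+ libraries lie between 1.36 and 1.87, and 1 WT library lies at 1.67.

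Camera with the preset correlation also called immune and metabolic lists at P14, but none of them held with an estimated correlation. By the exact permutation test of mean log2 CPM per library they had p = 0.0571 to 0.229 (Benjamini-Hochberg adjusted p = 0.333 to 0.421). That test has little reach with 4 libraries per group, since the deleted interval list had an adjusted p = 0.333 too. Interferon response genes (median -0.27, 29 of 34 lower, camera adjusted p = 7.32e-06; adjusted p = 0.320 with an estimated correlation) and genes of MHC class I presentation (median -0.45, mean -0.82, 15 of 15 lower, 8.24e-05; adjusted p = 0.545 with an estimated correlation) were lower in df/+. Log2 values were -0.66 for Xaf1, -0.52 for Ifit3, -0.81 for H2-K1 and -3.33 for H2-Q7, a near-identical copy of H2-Q6 whose single value is uncertain. With replicate 3 of P14 WT left out, H2-K1 was at -0.24 and H2-Q7 at -0.88. H2-K1 was at 201 ± 132 CPM in WT, where replicate 3 had 398, and at 115 ± 3.35 CPM in df/+. Cytosolic ribosomal proteins were lower by a median of -0.21 (52 of 52 genes, 4.96e-05; adjusted p = 0.771 with an estimated correlation), with Rpl7a at -0.27. Nuclear genes of oxidative phosphorylation were lower by -0.18 (2 of 53 higher, 0.00365; adjusted p = 0.801 with an estimated correlation), with Ndufa9 at -0.16. The 7 mitochondrially encoded genes were higher (0.32, 0.00135; adjusted p = 0.480 with an estimated correlation; mt-Nd1 0.58). So were cholesterol synthesis genes (0.10, 20 of 23 higher, 3.17e-04; adjusted p = 0.320 with an estimated correlation; Msmo1 0.29) and immediate early genes (0.16, 31 of 37 higher, 0.00599; adjusted p = 0.771 with an estimated correlation; Fos 0.56). No member of these lists was called over all genes or adjusted over the list alone. Without replicate 2 of P14 WT the oxidative phosphorylation and immediate early lists had adjusted p = 0.0909 and 0.0640. Without replicate 4 of P14 df/+ the immediate early list had 0.0558, and without replicate 3 of P14 WT the MHC list had a median of -0.16 (0.0782). Cell cycle (-0.12, 0.895), glycolysis and hypoxia (-0.06, 0.902), unfolded protein response (-0.04, 0.515) and histone lists (-0.07, 0.421) were not called. Without replicate 1 of P14 WT the cell cycle list was (-0.32, 1.93e-04).

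At P50 the same comparison was made in young adult mice. Of 9 genes called, 6 were interval genes that fell and 3 lay outside the interval. Nonagouti (gene symbol a), which encodes a secreted antagonist of melanocortin receptors that sets coat colour, rose, and Zswim1 and Spata25 fell. Nonagouti (chromosome 2, 154791402 to 155051012, GRCm38) had 541 reads over the 4 df/+ libraries and 1 read over the 4 WT libraries, a ratio of summed CPM of 498 with a 95% counting interval of 89.1 to 19717. Its level was 8.43 ± 6.03 CPM in df/+ (SD, n = 4) and its fitted log2 fold change was 8.46 (SE 0.864, edgeR adjusted p = 7.79e-04). Zswim1 (chromosome 2, 164822686 to 164826871) fell from 27.2 ± 7.64 to 11.7 ± 1.36 CPM (-1.22, SE 0.183, edgeR adjusted p = 0.0177). The overlapping gene Spata25 (164826389 to 164828537) fell from 7.95 ± 2.63 to 2.52 ± 0.583 CPM (-1.66, SE 0.276, adjusted p = 0.0377). As the strand used in counting is not known here, their 2 values are not independent. Zswim1 lost its call without replicate 2 or 4 of P50 WT (edgeR adjusted p = 0.0799 and 0.0988), without replicate 1 or 3 of P50 df/+ (0.0947 and 0.111), and with only the 8 P50 libraries (1.00). Spata25 lost it without replicate 2, 3 or 4 of WT (0.198, 0.0754, 0.144) or 1, 3 or 4 of df/+ (0.152, 0.150, 0.167), with the 8 P50 libraries (1.00), with no filter on low counts and with the length and GC offset. Nonagouti lost it only with the 8 P50 libraries (0.0947).

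At an unadjusted p under 0.05 there were 655 genes at P50, or 4.26% of those tested, under the share of 0.05 expected if no gene differed. Nos3 was at 482 ± 27.3 CPM in WT and 486 ± 101 CPM in df/+ (log2 fold change 0.01, SE 0.135), and Pecam1 at 1459 ± 126 and 1455 ± 222 CPM (0.00, SE 0.119). Kdr (-0.20, SE 0.234) and Gapdh (0.21, SE 0.240) were not called either (edgeR adjusted p = 1.00 for each of the 4). None of the 10 endothelial lists was called. Median log2 values were -0.04 for endothelial identity (camera adjusted p = 0.306), -0.02 for the blood-brain barrier (0.821), 0.04 for VEGF and tip cells (0.210), 0.00 for Notch and arterial genes (0.775) and 0.11 for venous genes (0.504). They were 0.03 for vasoreactivity (0.489), -0.06 for Wnt targets (0.489), 0.01 for TGF-beta and BMP signalling (0.774), 0.02 for basement membrane (0.223) and 0.07 for adhesion (0.267). The organic anion transporter Slc22a8 was at 1020 ± 59.3 CPM in WT and 799.8 ± 69.9 CPM in df/+ (-0.35, SE 0.104, adjusted p = 0.815) and was not called. Log2 values were 0.30 for the glucose transporter Slc2a1, -0.22 for Tie1, -0.33 for Erg, 1.03 for Igfbp3, 1.05 for Apln, 0.92 for Angpt2, 0.45 for Hsp90ab1 and 1.45 for Bdkrb2, with Apln at 0.18 without replicate 1 of P50 df/+ and Bdkrb2 at 0.84 without replicate 4. They were -0.51 for Edn3 (adjusted p = 0.734), 0.98 for P4ha2 (0.815) and 0.41 for Serpinh1 (0.856), and none was called. Without replicate 2 of P50 df/+ the VEGF and tip cell list (median 0.16, adjusted p = 7.52e-04), the basement membrane list (0.17, 7.52e-04) and the adhesion list (0.14, 0.0266) were called as higher in df/+. Without replicate 4 of P50 WT the Wnt targets were called as lower (-0.19, 0.0368). DESeq2 called Slc22a8 (0.0372). The count of 9 was 16 without replicate 2 of P50 df/+ (4 outside the interval) and 5 without replicate 2 or 4 of WT or replicate 3 of df/+. The 5 called genes of the interval list became 11 without replicate 2 of df/+ and 3 without replicate 2 or 4 of WT or 3 or 4 of df/+. DESeq2 called 30 genes (16 outside), 1 surrogate variable gave 35 (16 outside), the length and GC offset 16 (4 outside), and the 8 P50 libraries alone 0. The number range of the libraries and the genotype cannot be told apart at this age either.

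**Figure D4:**
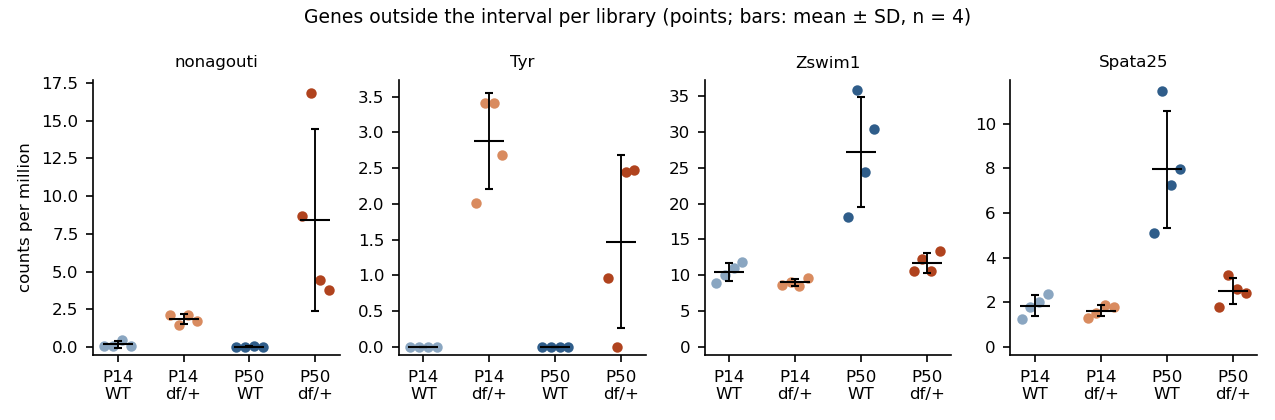
CPM of nonagouti, Tyr, Zswim1 and Spata25 (vertical axes) in each library of the 4 groups (horizontal axis); points are libraries and bars mean ± SD, n = 4. Tyr is at 0 in all 8 WT libraries, and nonagouti averages 8.43 CPM in P50 df/+.

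Unfolded protein response genes, chaperones and enzymes of the endoplasmic reticulum, were higher in df/+ (median 0.15, 18 of 26 higher, camera adjusted p = 0.00269; adjusted p = 0.547 with an estimated correlation), with Creld2 at 49.1 ± 8.54 and 66.7 ± 21.4 CPM and Pdia4 at 91.4 ± 12.2 and 108 ± 6.33 CPM. This call held without any 1 of the 8 P50 libraries. Genes of oxidative phosphorylation (0.28, 52 of 53 higher) and cytosolic ribosomal proteins (0.35, 51 of 52 higher) had the same adjusted p = 0.00269 (adjusted p = 0.846 with an estimated correlation for both). Log2 values were 0.95 for Atp5e, 0.83 for Uqcrq, 0.55 for Rps24 and 0.64 for Rps14 (-0.11, -0.12, -0.033 and -0.098 without replicate 2 of P50 df/+). Both rested on replicate 2 of P50 df/+, which has the steepest length slope: without it they were lower in df/+, with medians of -0.13 (0.00265) and -0.12 (9.59e-04). They also lost the call without replicate 1 of P50 WT (0.300 and 0.174), replicate 3 of P50 WT (0.145 and 0.171) or replicate 1 of P50 df/+ (0.439 for each). Mitochondrially encoded genes were lower (-0.34, 7 of 7, adjusted p = 0.0206; adjusted p = 0.846 with an estimated correlation; mt-Nd4 -0.53). This call was lost without replicate 1 of WT (0.337) and replicates 1 and 2 of df/+ (0.0571 and 0.417).

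MHC class I genes were lower at P50 too (median -0.43, mean -0.74, 14 of 15 lower, camera adjusted p = 0.00495; adjusted p = 0.846 with an estimated correlation). H2-Q6 was at 72.0 ± 118 CPM in WT, where replicate 2 had 248, and 8.33 ± 6.72 CPM in df/+ (-3.10, SE 1.12), and H2-Q7 had -3.00 (-0.67 and -0.74 without replicate 2 of WT). These 2 genes are near-identical copies and their single values are uncertain. The list was not called without replicate 2 of WT (median -0.10, 0.487) or replicate 3 or 4 of df/+ (0.245, 0.251). Pericyte markers were higher (0.19, 15 of 16, 0.0113; Higd1b 0.74, or 0.15 without replicate 2 of df/+, Kcnj8 0.34), as were glycolysis and hypoxia genes (0.23, 23 of 30, 0.0495). Lymphocyte and neutrophil markers were lower (-0.88, 7 of 8, 0.00269; Cd4 -1.35). With an estimated correlation these had adjusted p = 0.846, adjusted p = 0.846 and adjusted p = 0.765. Pericyte markers lost the call without replicates 1 or 2 of WT (0.152, 0.146) or 1 or 4 of df/+ (0.0621, 0.311). Glycolysis lost it without replicate 1 of WT (0.300) or 1 or 2 of df/+ (0.311, 0.343), and lymphocyte markers without replicates 2, 3 or 4 of df/+ (0.0800, 0.0933, 0.0610). Microglia (median 0.33, 0.113; Trem2 1.67, or 0.59 without replicate 2 of df/+, Tyrobp 0.72), perivascular macrophage (0.09, 0.775), astrocyte (0.00, 0.540), neuron (-0.07, 0.741), oligodendrocyte (0.21, 0.259), precursor (0.05, 0.774), fibroblast (0.14, 0.489), smooth muscle (0.17, 0.147), erythrocyte (0.49, 0.0652) and ependymal markers (0.46, 0.0652) were not called. Neither were interferon response (-0.05, 0.220), cell cycle (0.23, 0.168), cholesterol synthesis (0.19, 0.143), immediate early (-0.20, 0.775) and histone genes (0.18, 0.211). Single omissions brought calls to some of these. Microglia markers were called without WT 1, WT 2 or df/+ 3 (0.0241, 0.0354, 0.0348), ependymal without WT 2, WT 4 or df/+ 4 (0.0117, 0.00671, 0.00111), and erythrocyte without WT 2, WT 4 or df/+ 4 (0.0354, 0.0170, 0.00333). Smooth muscle markers were called without WT 4 or df/+ 4 (0.00748, 0.0341), and immediate early genes without WT 1, where the median turned to 0.031, WT 3 or WT 4 (0.0331, 0.0412, 0.00671). Called without 1 library each were astrocyte (WT 4, 0.0462), oligodendrocyte (df/+ 3, 0.0455), interferon (WT 1, 0.00547), cell cycle (df/+ 2, 6.14e-04), cholesterol (df/+ 4, 0.0395) and histone genes (df/+ 3, 0.0335). No list member outside the interval was called over all genes at P50. Adjusted over the list alone, 1 gene each of the cholesterol and erythrocyte lists passed.

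The genotype effect averaged over both ages is the genotype comparison in which the library numbers are balanced. It called 18 genes, of which 15 were interval genes that fell. Outside the interval nonagouti and Tyr rose and Zswim1 fell. In all, 639 genes (4.16%) were at an unadjusted p under 0.05, under the share of 0.05 expected if no gene differed. Nonagouti had an averaged log2 fold change of 5.91 (SE 0.551, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.51e-05). At P14 it had 107 reads in df/+ and 10 in WT, a ratio of 11.3 with a 95% counting interval of 5.91 to 24.2. Of the 10 WT reads 7 were in replicate 3, and with that library left out the ratio was 28.2 (9.40 to 139). Tyr, which encodes tyrosinase, the first enzyme of melanin synthesis (chromosome 7, 87424771 to 87493512), had 0 reads in all 8 WT libraries. In df/+ it had 156 reads at P14 (2.88 ± 0.676 CPM, at least 54.9-fold higher against a floor of 3 reads over the WT group) and 105 reads at P50 (1.47 ± 1.21 CPM, at least 32.2-fold higher), with 0 reads in replicate 2 of P50 df/+. Its averaged adjusted p was 0.0333 in edgeR, and 0.232 with the replicate number as a block (1.38e-11 to 0.232 over its alternatives). Zswim1 had an averaged log2 fold change of -0.71 (edgeR adjusted p = 0.0473) and was not called with RLE or upper-quartile scaling, with either other filter, with the bias-adjusted test or with limma-voom (adjusted p over all its alternatives 5.76e-04 to 0.156). Of 16 omissions of 1 library, Tyr kept its call in 2 (highest adjusted p = 0.0965) and Zswim1 in 2 (highest 0.156), while nonagouti kept it in all 16. The count was 14, with 1 gene outside the interval, without replicate 2, 3 or 4 of P14 WT, any replicate of P14 df/+, replicate 2 or 4 of P50 WT or replicate 4 of P50 df/+. It was 36 without replicate 1 of P14 WT (20 outside the interval), 34 with DESeq2 (13 outside) and 33 with 1 surrogate variable (12 outside).

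Of the lists, 13 were called in the averaged comparison, and the deleted interval (median -1.03, camera adjusted p = 1.50e-82) was the one that held with an estimated correlation (adjusted p = 3.86e-04). Microglia (0.95, 5.15e-19) and perivascular macrophage markers (0.82, 3.46e-08) were higher, each with adjusted p = 0.193 with an estimated correlation. Astrocyte (0.26, 2.63e-05), oligodendrocyte (0.25, 1.15e-04), precursor (0.31, 0.0114), fibroblast (0.15, 0.0190), smooth muscle (0.15, 0.0221) and cholesterol synthesis lists (0.16, 7.02e-04) were higher. Interferon response (-0.17, 1.73e-04) and MHC class I genes (-0.46, 15 of 15 lower, 6.78e-06) were lower. These 8 lists each had adjusted p = 0.542 with an estimated correlation. Neuron (0.33, 0.0190) and erythrocyte markers (0.40, 0.0221) were higher, with adjusted p = 0.620 and adjusted p = 0.558 with an estimated correlation. The microglia, macrophage and oligodendrocyte medians were 1.61, 1.38 and 1.05 without replicate 1 of P14 WT. Single libraries ended 5 of these calls. Neuron markers lost the call without P14 WT 3, P14 df/+ 1, P50 WT 3, P50 df/+ 1 or P50 df/+ 2 (0.103, 0.737, 0.119, 0.199, 0.101). Erythrocyte markers lost it without P14 WT 3, P14 WT 4, P14 df/+ 1, P14 df/+ 3, P50 WT 1, P50 df/+ 1 or P50 df/+ 2 (0.0563, 0.0545, 0.0756, 0.0528, 0.193, 0.199, 0.242). Smooth muscle markers lost it without P14 WT 1, P14 WT 2, P14 df/+ 3, P50 WT 1, P50 WT 3 or P50 df/+ 2 (0.104, 0.0919, 0.0981, 0.111, 0.119, 0.242). Fibroblast markers lost it without P14 WT 3, P14 df/+ 1, P50 WT 1, P50 WT 3 or P50 df/+ 1 (0.0562, 0.104, 0.0621, 0.119, 0.226), and precursor markers without P14 WT 3, P14 df/+ 1, P14 df/+ 2 or P50 WT 1 (0.0612, 0.0756, 0.0536, 0.0584).

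Whether the genotype effect differed between the ages was tested by the interaction. It called 0 genes with edgeR, 0 with DESeq2 and 0 with limma-voom. In edgeR 305 genes (1.98%) had an unadjusted p under 0.05, under the share of 0.05 expected if no gene differed. Across 15339 genes outside the interval, the log2 fold changes at P14 and P50 correlated with Pearson 0.144 and Spearman 0.0339 (across genes, which are not independent replicates), and 50.5% had the same sign. Camera called 12 lists. The genotype difference at P50 minus that at P14 was lower for microglia (median -1.07, adjusted p = 3.82e-12), perivascular macrophage (-1.28, 3.38e-08), astrocyte (-0.33, 7.04e-04), neuron (-0.95, 6.16e-04) and precursor markers (-0.45, 8.07e-04). It was higher for ribosomal proteins (0.58, 3.38e-08), oxidative phosphorylation (0.45, 3.81e-06) and the unfolded protein response (0.18, 0.00204). With an estimated correlation each of the 12 had an adjusted p of 0.419 to 0.823, and fry called 0 lists. Without replicate 2 of P50 df/+ the ribosomal (0.10, 0.678) and oxidative phosphorylation lists (0.05, 0.874) were not called. Neuron markers were not without replicate 1 of P14 df/+ or 3 of P50 df/+ (0.128, 0.107), and astrocyte markers not without replicate 4 of P50 WT or 3 of P50 df/+ (0.0775, 0.104). The interaction and the number range of the libraries cannot be told apart.

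The effect of age was measured in the WT libraries, P50 against P14. The P14 WT libraries had numbers up to 8 and the P50 WT libraries numbers from 9, an order that is reversed in df/+. The comparison called 3865 genes, 25.1% of those tested. Of these, 2013 rose and 1852 fell, and 2175 of them changed by 2-fold or more. Xdh, which encodes xanthine dehydrogenase (chromosome 17, 73883895 to 73950196), rose from 7.26 ± 3.84 to 405 ± 114 CPM (SD, n = 4; log2 fold change 5.81, edgeR adjusted p = 4.37e-07). Slfn2, Cntn2 and Hapln2 rose by 4.68, 5.21 and 4.59 on the log2 scale (adjusted p = 9.73e-07, 5.00e-04 and 0.00123). In a fit that left out replicate 1 of P14 WT, Cntn2 and Hapln2 were at 7.75 and 7.55 and still called. Both are known from myelinated axons, and the oligodendrocyte and myelin list, which does not hold them, was called as higher at P50 in the same libraries (median 1.00, camera adjusted p = 7.54e-04; adjusted p = 0.773 with an estimated correlation). Cyp2e1, a cytochrome P450, and Nrsn2 had 2 and 3 reads over the P14 libraries and 423 and 265 at P50. The ratios were 194 (95% counting interval 53.5 to 1610) and 81.2 (27.5 to 396), the first at 306 (54.6 to 12104) without replicate 1 of P14 WT and the other at 185 (32.9 to 7322) without replicate 4. Lrrc55 (chromosome 2, 85162334 to 85197197) fell from 100.1 ± 34.2 to 0.271 ± 0.190 CPM (-8.44, adjusted p = 3.35e-08, and -9.09 without replicate 4 of P50 WT). Ackr2, a scavenging chemokine receptor (chromosome 9, 121898355 to 121911074), fell from 109 ± 5.87 to 0.412 ± 0.112 CPM (-8.03, 4.69e-09). Madcam1, an adhesion molecule for leukocytes, fell from 28.1 ± 3.45 to 0.203 ± 0.0856 CPM (-7.04, 5.30e-08). Tacr3, Neil3 and Kif2c had 262, 301 and 325 reads at P14 and 1, 2 and 4 at P50. The ratios were 285 (50.7 to 11302), 164 (44.9 to 1358) and 88.4 (34.2 to 326), that of Kif2c at 269 (47.9 to 10638) without replicate 2 of P50 WT. The read of Tacr3 at P50 was in replicate 1. Of the qPCR genes, Kdr fell from 2582 ± 140 to 901 ± 236 CPM (-1.52, SE 0.239, adjusted p = 2.36e-04). Nos3 (0.04, SE 0.135), Pecam1 (0.08, SE 0.119) and Gapdh (-0.11, SE 0.240) were not called.

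Cell cycle, VEGF and tip cell, and basement membrane lists were called as lower at P50, and interferon response and MHC class I lists as higher. Of 38 cell cycle genes 32 fell, 34 adjusted over the list alone (median -2.61, camera adjusted p = 2.30e-20; adjusted p = 0.121 with an estimated correlation). Among them Cdk1 fell from 38.6 ± 9.97 to 1.26 ± 0.665 CPM, Ccna2 (-3.67) and Ccnb2 (-5.83). Of 31 VEGF and tip cell genes 20 fell and 2 rose, 23 adjusted over the list alone (-1.52, 6.55e-11; adjusted p = 0.0831 with an estimated correlation). Mcam fell from 600.4 ± 12.2 to 137 ± 8.45 CPM, and Adm fell by 2.82 on the log2 scale. Of 33 basement membrane and matrix genes 21 fell and 4 rose, 25 adjusted over the list alone (-0.96, 2.81e-10; adjusted p = 0.121 with an estimated correlation). The laminin chain Lamb1 fell from 614 ± 39.8 to 48.6 ± 6.79 CPM, Lama4 from 999 ± 51.3 to 179 ± 38.5 CPM, and the integrin Itga5 by 1.81. Of 34 interferon response genes 31 rose, 32 adjusted over the list alone (1.78, 1.02e-19; adjusted p = 0.0609 with an estimated correlation). Ifit3 was at 3.45 ± 0.572 and 69.4 ± 22.1 CPM and Irf1 at 1.54. All 15 MHC class I presentation genes rose, over all genes and adjusted over the list alone (1.63, 3.79e-09; adjusted p = 0.371 with an estimated correlation), including H2-T23 (1.63), Tap2 (1.60) and Psmb9 (2.35).

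The smooth muscle, ependymal and choroid plexus, neuron and oligodendrocyte lists were called as higher at P50 in the same libraries. Of 16 smooth muscle markers 11 rose and 1 fell, 15 adjusted over the list alone (median 1.74, camera adjusted p = 1.29e-06; adjusted p = 0.121 with an estimated correlation). Acta2 was at 46.9 ± 11.7 and 173 ± 51.4 CPM, Sncg at 3.74 and Lmod1 at 2.00. Of 14 ependymal and choroid plexus markers 11 rose, 12 adjusted over the list alone (2.98, 1.73e-04), including Prlr (4.09) and Kcnj13 (3.49). Of 20 neuron markers 4 rose, 6 adjusted over the list alone (1.16, 0.00227; Stmn2 1.79, Nrgn 1.17), and of 16 oligodendrocyte and myelin markers 4 rose, 5 adjusted over the list alone (1.00, 7.54e-04; Mobp 3.38, Mal 1.41). Immediate early and dissociation genes had 19 that rose and 2 that fell of 37, 25 adjusted over the list alone (1.08, 1.92e-04), with Hspa1a at 31.5 ± 22.4 and 634 ± 166 CPM, Hspb1 at 2.67 and Myc at -3.43. These 4 lists each had adjusted p = 0.773 with an estimated correlation. Myelin basic protein Mbp rose from 2216 ± 2088 to 12540 ± 5431 CPM (edgeR adjusted p = 0.00504), the highest level among these markers. With replicate 1 of P14 WT left out, Mbp and Mobp rose by 3.40 and 4.81 on the log2 scale.

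Lists of endothelial specialisation held members that moved in both directions. Of 33 endothelial identity genes 4 rose and 8 fell (median -0.15, camera adjusted p = 0.171). Ly6a rose from 287 ± 12.9 to 1677 ± 396 CPM, Vwf fell by 0.78 and Ecscr fell by 1.60 on the log2 scale. Of 33 blood-brain barrier genes 6 rose and 9 fell (-0.04, 0.293). The monocarboxylate transporter Slc16a1 fell from 4999 ± 244 to 680 ± 130 CPM (-2.88, edgeR adjusted p = 2.03e-07). The amino acid transporter Slc7a5 fell from 4956 ± 189 to 2170 ± 320 CPM (-1.19). Of 27 Notch and arterial genes 11 rose and 9 fell (median -0.30, mean 0.18, 0.917). The alkaline phosphatase Alpl rose from 15.5 ± 3.75 to 295 ± 57.0 CPM (4.25, adjusted p = 4.69e-09), and Nrarp fell by 1.47. Of 33 vasoreactivity genes 8 rose and 7 fell (0.04, 0.772), with the purine receptors P2ry1 and P2ry2 rising by 3.32 and 3.00. Wnt targets (6 rose, 5 fell, 0.417), TGF-beta and BMP genes (6 and 7, 0.426), venous genes (5 and 5, 0.396) and adhesion genes (4 and 1, 0.647) were not called as lists. Neither were astrocyte (5 and 2, 0.205), pericyte (2 and 6, 0.159), fibroblast (2 and 4, 0.243), precursor (0 and 4, 0.243), microglia (0 and 2, 0.553), perivascular macrophage (0 and 1, 0.907), glycolysis (3 and 7, 0.159), cholesterol (4 and 2, 0.553) and unfolded protein response genes (4 and 6, 0.647). All 10 called lists held without any 1 of the 8 WT libraries. Without replicate 1 of P14 WT the microglia (1.34, 0.00516), mitochondrial genome (0.91, 0.00923) and ribosomal lists (-0.26, 0.0468) were called too. Without replicate 3 of P50 WT the mitochondrial genome was called (0.80, 0.0287) and without replicate 4 of P50 WT the ribosomal list (-0.38, 0.0104). With all libraries they had adjusted p = 0.553, 0.0899 and 0.159.

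**Figure D5:**
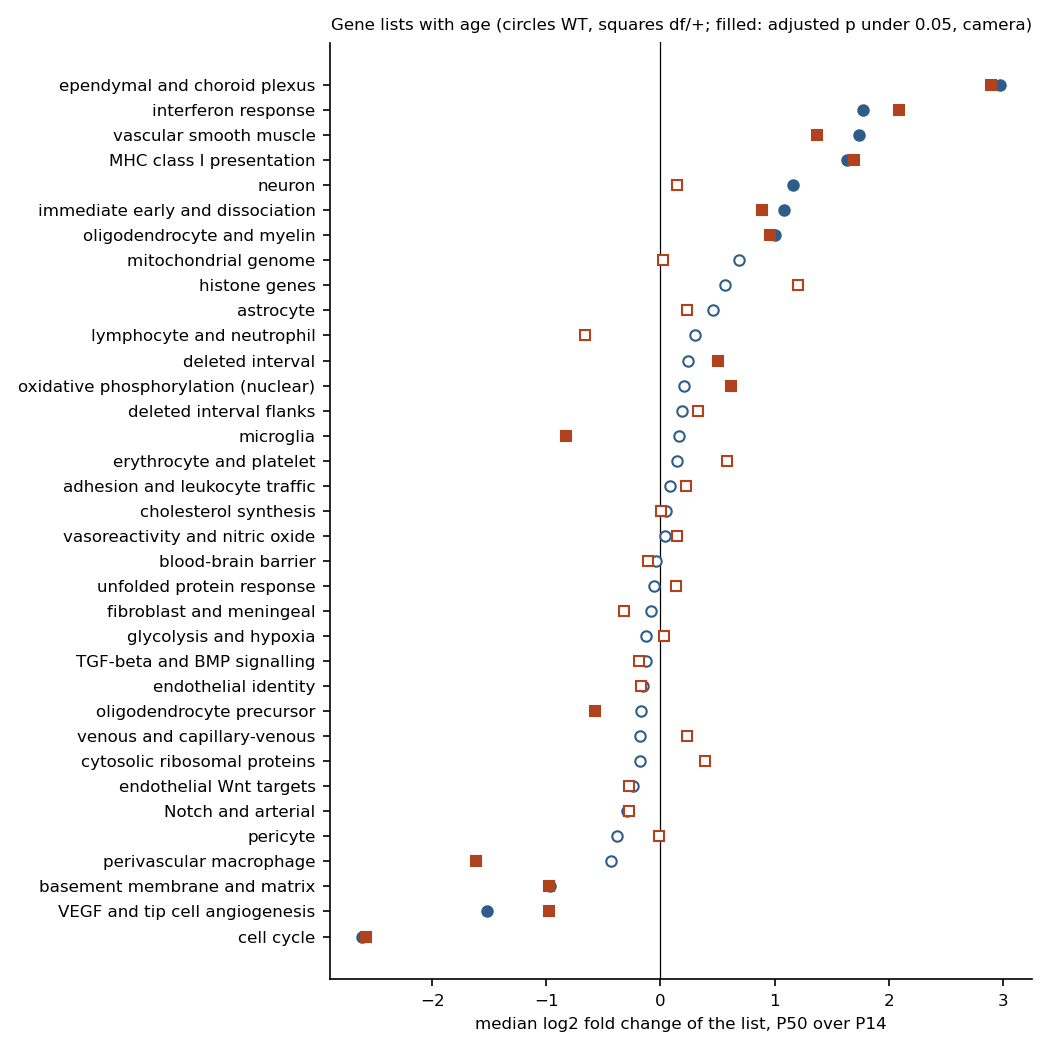
Median log2 fold change of P50 over P14 (horizontal axis) for each of the 35 tested lists (vertical axis), with circles for WT and squares for df/+, filled where the camera adjusted p is under 0.05. Cell cycle lies lowest (-2.61 in WT, -2.58 in df/+) and ependymal and choroid plexus markers highest (2.98 and 2.90).

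In df/+ cells age called 4512 genes, of which 2561 rose and 1951 fell, 2400 of them by 2-fold or more. Across genes, the age effects in WT and df/+ correlated with Pearson 0.879 and Spearman 0.828 (genes are not independent replicates). Both genotypes called 1588 genes up and 1501 genes down. Independent lists of these sizes would share 335 and 235. Here 0 genes were called in opposite directions, although the library numbers ran from 9 at P14 and up to 8 at P50 in df/+ and the other way in WT, so that an effect of the number range alone would give opposite directions. The 0 genes of the interaction test are the test of a difference between the 2 age effects.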

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

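The weighing of the microglia markers, the tests of coat-colour markers and of an equal mix in the P50 df/+ library, and the splits for lists with age in df/+ and for the adjusted p of the interval list at P50 were chosen after the results were seen. The other splits of the libraries were set before. For the other tests of the P50 df/+ library and those of the gene neighbourhoods, the bounds were set before these tests were run. The patterns they address had been seen by then, and the length and GC correction was chosen after seeing the data.

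Of 513 groups of 4 libraries examined for 1 library far from the other 3 (Dixon's test), 45 had such a library: 37 of 349 for genes, 6 of 140 for lists and 2 of 24 for library measures. This test picks out about 1 in 20 groups by chance. Replicate 1 of P14 WT accounted for 16 of them. It was high for the immune genes P2ry12 (6.26 CPM, others up to 1.10), Csf1r (46.8, others up to 9.65), Ctss (9.19, others up to 1.87) and Cd163 (9.03, others up to 2.48), for the myelin and neural genes Mbp (5315 CPM), Mobp (988.6), Mal (471), Cntn2 (3.96), Hapln2 (1.58), Tnr (40.6) and Snap25 (3.72), and for Mylpf (7.13). It was low for Pecam1 (1300 CPM, others 1397 to 1413), AI467606 (41.8), the cell cycle list (mean log2 CPM -0.81 relative to WT) and the endothelial identity list (-0.11).

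Higher microglia and macrophage markers in P14 df/+ libraries were weighed against 3 technical explanations; CD45 beads, which should remove these cells, were part of the isolation. A generally lower purity would raise markers of every other cell type alike, but the df/+ minus WT difference of the microglia list exceeded that of the pericyte list by 1.81 (SE 0.552, mean log2 CPM). On the same measure the oligodendrocyte (0.98, SE 0.825), precursor (0.59), neuron (0.51), astrocyte (0.43) and fibroblast lists (0.30) were higher in df/+. Of the lists of other cell types only pericyte (-0.12) and ependymal (-0.18) were lower. The pericyte list alone therefore cannot decide, and a lower purity stays open. An effect of the library number (1 to 8 or 9 to 16) of equal size at the 2 ages would give opposite differences, but these summed to 1.89 (SE 0.664) instead of 0. Such an equal effect alone does not account for the pattern. An effect of the number range at P14 only cannot be told apart from the genotype. Less complete removal of CD45-positive cells may contribute and cannot be told apart from more microglia or macrophages near the vessels of df/+ mice, which was not tested: the list of lymphocytes and neutrophils, which carry CD45 too, had a df/+ minus WT difference of 0.14 (SE 0.370, mean log2 CPM), but its 8 tested genes had a median level of 1.32 CPM, too low to decide. Without replicate 1 of P14 WT, whose Csf1r (46.8 CPM) and P2ry12 (6.26 CPM) lay within the range of the df/+ libraries, 73 genes were called at P14, of which 58 rose, 15 of them in the microglia or macrophage lists, 5 in the oligodendrocyte lists and 1 in the endothelial lists.

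Replicate 2 of P50 df/+ was far from the other 3 in the endothelial identity list (-0.34, others -0.01 to 0.03), the share of mitochondrial reads (1.32%, others 2.15% to 2.25%), Creld2 (98.7 CPM) and the interval gene Maz (168 CPM, others 116 to 124). Its weaker loss of interval reads (0.710 times WT) was weighed against the length and GC trend and 1 WT mouse in the pool of 2. After the length and GC correction its interval ratio was -0.79 (bootstrap SE over genes 0.140, log2), between the bounds set for the trend (under -0.80) and for the mouse (above -0.60) and within 2 SE of both. Equal parts of cells from 1 WT and 1 df/+ mouse would give -0.42, from which the corrected ratio differed by -0.37 (2.67 SE). This SE covers the spread between genes of 1 library and not the error of the correction. Before the correction the ratio was -0.49, so an equal mix is not excluded. The trend and a part of WT cells may each account for some of the weaker loss and cannot be told apart here. Its nonagouti level, 16.9 CPM, was the highest of all libraries, while it held 0 reads of Tyr. Ttr held more counts than any other gene in this library (3.90%), in replicate 4 of P50 WT (1.77%) and in replicate 1 of P50 df/+ (1.66%). These were the P50 libraries with the lowest length slopes (-0.481, -0.234 and -0.222). Carry-over of other tissue was not weighed for them.

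Nonagouti and Tyr reads in df/+ libraries were weighed against 2 explanations. A change of the chromosomal neighbourhood is argued against for nonagouti by the 19 tested genes within 500 kb, of which 0% had an unadjusted p under 0.05 in the averaged comparison, while near Tyr only 2 genes were tested (Nox4 0.42, SE 0.399, and Grm5 0.21, SE 0.519; 0% under 0.05), too few to decide. Coat-colour marker genes on the engineered chromosome, as vectors of chromosome engineering can carry them, were not put to a test that decides: that 7 of 8 df/+ libraries, but 0 WT libraries, held 10 or more reads of both genes restates the pattern. The reads, which could show vector sequence, were not used here, so this stays open beside an effect of the deletion on both genes. Nonagouti was also far from the others in replicate 3 of P14 WT (0.482 CPM) and replicate 3 of P50 WT (0.0698 CPM, 1 read).

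The remaining single libraries were as follows. In P14 WT, replicate 2 had Slc7a5 at 5237 and H2-T23 at 90.7 CPM, replicate 3 had H2-K1 at 398 and H2-Q7 at 8.33 CPM, and replicate 4 had Sncg at 2.07 CPM. In P14 df/+, replicate 1 had Aldoa at 231, Gad2 at 3.53 and Snap25 at 23.8 CPM, replicate 2 had Slx1b at 5.17 CPM and replicate 3 had Ypel3 at 42.6 CPM. In P50 WT, replicate 1 had Tacr3 at 0.0631 CPM, replicate 2 had H2-Q6 at 248, H2-Q7 at 164 and Tie1 at 1450 CPM, replicate 3 had Edn3 at 168 and P4ha2 at 50.2 CPM and 5.88% of counts in its 10 most abundant genes, and replicate 4 had Slfn2 at 32.0 CPM, the adhesion list at -0.37 and the endothelial identity list at -0.10. In P50 df/+, replicate 1 had Apln at 69.3 and Cdiptos, which overlaps Cdipt, at 0.0564 CPM, and the MHC class I list at -0.021 where the others lay at -0.78 to -0.71.

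The genotype effect differed between the ages for 12 lists by camera (adjusted p = 3.82e-12 to 0.0423). The P50 effect minus the P14 effect (median log2) was 0.58 for ribosomal proteins, 0.45 for oxidative phosphorylation, 0.27 for pericyte markers, 0.18 for the unfolded protein response, -0.20 for oligodendrocyte, -0.33 for astrocyte, -0.45 for precursor, -0.62 for lymphocyte, -0.95 for neuron, -1.07 for microglia and -1.28 for perivascular macrophage markers, and -0.67 for mitochondrially encoded genes. With an estimated correlation no list was called (adjusted p = 0.419 to 0.823). Ribosomal and oxidative phosphorylation lists lost the call without replicate 2 of P50 df/+ (0.678 and 0.874). Neuron markers lost it without P14 df/+ 1 or P50 df/+ 3 (0.128, 0.107), and astrocyte markers without P50 WT 4 or P50 df/+ 3 (0.0775, 0.104). Lymphocyte markers lost it without P14 WT 3, P14 df/+ 1, P50 df/+ 3 or P50 df/+ 4 (0.114, 0.0569, 0.107, 0.0660). Oligodendrocyte markers lost it without P14 WT 2, 3 or 4, P14 df/+ 1 or 3, P50 WT 1 or 2, or P50 df/+ 3 or 4 (0.0956, 0.465, 0.183, 0.154, 0.202, 0.132, 0.102, 0.699, 0.124).

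Other splits of the same libraries were fitted to see whether a grouping by chance gives results as large. The real split was the largest for members of the fixed interval list at P14 (9 called, 1 of 35 splits as large, the real one, highest other 0), for age in WT (3865 genes, 1 of 35, highest other 0) and for age in df/+ (4512 genes, 1 of 35, highest other 3). For the P50 interval list it had the smallest camera adjusted p (6.16e-48, 1 of 35 as small, the real one, smallest other 2.03e-17), a measure chosen after the results were seen. A share of 1 of 35 is the smallest that these splits allow. Every other split mixes the groups and so adds their difference to the spread. These splits therefore speak against chance without excluding it. For the averaged genes 4 of 100 drawn splits were as large (18 in the real one, 31, 5034 and 5433 in the others), a share under 0.05 by a margin within its sampling error, so chance is not firmly excluded. For the interaction the splits decide nothing, since the real count is 0 and any split is as large (100 of 100, highest other 3722). Chance was not excluded for the gene counts at P14 (10, 2 of 35, highest other 15) and P50 (9, 4 of 35, highest other 7438), members of the interval list at P50 (5, 2 of 35, highest other 5, in the split that called 7438 genes), or the numbers of lists at P14 (15, 10 of 35, highest other 19), at P50 (9, 24 of 35, highest other 13), averaged (13, 36 of 100, highest other 19), by interaction (12, 42 of 100, highest other 19), with age in WT (10, 30 of 35, highest other 22) and with age in df/+ (14, 8 of 35, highest other 16). The number of lists called cannot decide, for age or for genotype. With age in WT the real split called 3865 genes and the others at most 0, yet 30 of 35 splits called as many lists. The P50 split with 7438 genes set replicates 1 and 3 of WT and 3 and 4 of df/+ against the other 4. The former are the P50 libraries with length slopes above 0, so this split points to a structure of the P50 libraries across genotypes. The averaged split with 5433 genes also points to a structure of the libraries, since it called many times the real count. The P14 split with 15 genes put replicate 1 of WT together with replicates 1, 2 and 3 of df/+.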

How the results depend on the processing

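The length and GC offset, the newer quasi-likelihood method and the fit without 2 doubted libraries were chosen after seeing the data. All 1071 alternatives for the named genes with age in WT left the call or its absence unchanged, and called genes kept their direction. The direction of uncalled genes, such as Nos3, Pecam1 and Gapdh, is not covered by this count. The deleted interval list was called as lower under all 21 alternatives at P14 (median -1.18 to -1.06) and at P50 (-1.17 to -0.82), nonagouti ranged from 5.50 to 6.69 (averaged, log2), and no scaling moved the median of all genes by over 0.1. Small changes can be missed: in the P14 and P50 simulations 10.4% and 14.9% of 1.5-fold and 41.8% and 37.3% of 2-fold changes were called. These changes were in genes with a mean of at least 2 CPM, and genes under that level were not tried. Depth and the number of libraries per group were not varied there. The cause was not tested for any change that follows, except that fewer libraries leave less power.

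Numbers in brackets count members of the fixed interval list. With upper-quartile scaling P14 had 5 calls (4). DESeq2 gave 23 (14) at P14, 30 (13) at P50 and 34 averaged, and shared all 10, 9 and 18 calls. With only the 8 libraries compared, P14 had 22 (17), P50 0 (0) and age in df/+ 2417. With 1 surrogate variable P14 had 21 (17), P50 35 (18), averaged 33 and age in WT 7326. The length and GC offset gave P50 16 (11). Without replicate 1 of P14 WT and replicate 2 of P50 df/+ together, P14 had 137 (16), P50 18 (12) and averaged 72, and the medians turned to -0.13 for oxidative phosphorylation and -0.12 for ribosomal proteins at P50 and -0.18 for oxidative phosphorylation averaged. With an estimated correlation camera called 3 lists at P14, 1 at P50, 1 averaged, 0 by interaction and 0 with age in WT or df/+; fry called 1, 1, 1 and 0 in the first 4. With 1 surrogate variable the median of ribosomal proteins with age in df/+ turned to -0.16. Lists were not rerun with DESeq2.

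Leaving out 1 library gave 3 to 73 genes at P14 (73 without replicate 1 of WT), 3 to 14 interval list members at P14, 5 to 16 genes and 3 to 11 list members at P50 (16 and 11 without replicate 2 of df/+), 14 to 36 averaged genes (36 without replicate 1 of P14 WT), 0 interaction genes, 2911 to 3725 genes with age in WT, 3323 to 5577 with age in df/+, 14 to 17 lists at P14, 10 to 17 averaged, 11 to 16 by interaction, 10 to 13 with age in WT, 11 to 17 with age in df/+ and 4 to 15 lists at P50 (4 without replicate 1 of df/+, 15 without replicate 4 of WT). Among lists called with all libraries or with 1 left out, the direction of the test changed for ependymal at P14 without df/+ 2 (medians over the omissions -0.086 to 0.84). It also changed for immediate early at P50 without WT 1 (-0.41 to 0.033, and 0.031 without WT 1). Oxidative phosphorylation changed without P50 df/+ 2, with ranges of -0.13 to 0.48 at P50, -0.14 to 0.18 averaged and 0.045 to 0.63 by interaction. Ribosomal proteins changed without P50 df/+ 2 at P50 (-0.12 to 0.58) and without P50 df/+ 3 or 4 averaged (-0.17 to 0.18).

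The replicate number as a block gave 3 genes at P14, with 3 members of the interval list, and 3 list members at P50; it left P50 at 7 (3 outside the interval), averaged at 17, the interaction at 0, age in WT at 3772 and age in df/+ at 4193. Among lists it added TGF-beta and BMP at P14 (adjusted p = 0.0407) and ended glycolysis at P50 (0.0628), and it ended the averaged call of Tyr (0.232). The block changed no other call of a named list, nor any named gene with age in WT, where the same-number correlations passed the rule for pairs. Outside the WT age comparison, same-number correlations were -0.17 to 0.23 for the genotypes at P14, -0.55 to 0.49 at P50 and -0.14 to 0.22 for the ages in df/+, with 2 of 4 libraries best with their own number in each, so these libraries share only a number.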

Other observations

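Age in df/+ cells was chosen for a closer description after the results were seen. In df/+ cells, interferon and MHC class I genes rose with age, and cell cycle, vessel growth and matrix genes fell. Of 34 interferon response genes 31 rose (median log2 fold change 2.09, camera adjusted p = 5.35e-20; adjusted p = 0.0547 with an estimated correlation), all 15 MHC class I genes rose (1.70, 7.59e-09), 32 of 38 cell cycle genes fell (-2.58, 9.21e-18), 18 of 31 VEGF and tip cell genes fell and 3 rose (-0.97, 7.59e-09), and 20 of 33 basement membrane genes fell and 3 rose (-0.98, 1.50e-08). With an estimated correlation these 4 had adjusted p = 0.386, 0.180, 0.168 and 0.180. Kdr fell by 1.78 on the log2 scale in df/+ cells and by 1.52 in WT.

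Some markers of brain macrophages and of oligodendrocyte precursors fell with age in df/+ cells: 6 of 10 perivascular macrophage markers (median -1.61, camera adjusted p = 0.00434; adjusted p = 0.592 with an estimated correlation), 3 of 20 microglia markers (-0.83, 0.00484; adjusted p = 0.769 with an estimated correlation) and 6 of 13 precursor markers (-0.58, 0.00754; adjusted p = 0.592 with an estimated correlation). In WT the medians were -0.43, 0.16 and -0.17 and none of these lists was called. The nuclear oxidative phosphorylation list was higher at P50 in df/+ (16 of 53 rose, median 0.62, 0.00252; adjusted p = 0.779 with an estimated correlation), but without replicate 2 of P50 df/+ it was not called (0.21, adjusted p = 0.364). Smooth muscle (12 rose, 1 fell) and ependymal markers (13 of 14 rose) were called as higher at P50 in df/+ (1.37 and 2.90, adjusted p = 1.82e-06 and 6.60e-06; adjusted p = 0.180 and 0.592 with an estimated correlation). The other lists given here for df/+ kept their call without any 1 of the 8 df/+ libraries. The difference between the genotypes in these age effects is the interaction given in the report. It was not called for smooth muscle (camera adjusted p = 0.983) or ependymal markers (0.0712), but the latter were called in 6 of 16 omissions of 1 library: P14 WT 3, P14 df/+ 3 or 4, P50 WT 2 or 4, or P50 df/+ 4 (0.0352, 3.56e-04, 0.00407, 0.0173, 0.0120, 0.00437).

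The labels give no sex of the mice. Xist, which is expressed from the inactive X chromosome of female cells, had at most 4 reads in any library, and the Y-linked gene Eif2s3y was at 29.7 to 49.4 CPM in all 16. Ddx3y, another Y-linked gene, was at 64.4 to 100.7 CPM at P14 and 21.9 to 94.1 CPM at P50.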
